A study of Mus musculus with 15 samples.

How the data were processed

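Gene expression was measured by sequencing oligo(dT)-selected messenger RNA, primed with random hexamers, of bone marrow-derived dendritic cells of C57BL/6 mice. The 15 libraries form 5 groups of 3: unstimulated, yeast-locked C. albicans, hyphae-locked C. albicans, and β-glucan-coated beads of 6 µm and of 25 µm. The deposited table holds counts, whole-number raw counts per gene with 1 column per library, and the authors name STAR 2.7.7a, R 4.0.2, featureCounts, DESeq2 1.28.1 and the builds GRCm38 and mm10 in their processing notes without saying which step each served. Annotation release, strand setting, treatment of reads that map to several places, the amounts of C. albicans and beads, and whether the libraries of a group came from separate cultures or animals are not given in the sources used here. No group with uncoated beads was analysed here, and no column of the table was left out.

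Counts were analysed with R 4.3.3, edgeR 4.0.16 and limma 3.58.1. Of 24421 genes, filterByExpr with the 5 groups kept 13059. Libraries were scaled with TMM, whose factors ran from 0.847 (hyphae) to 1.09 (unstimulated), and a quasi-likelihood model with 1 term per group was fitted to all 15 libraries. Contrasts were each stimulus against unstimulated, hyphae against yeast, 25 µm against 6 µm beads, and the difference of these last size contrasts. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes; SE was derived from the F statistic and CPM used TMM-scaled library sizes. Gene lists were tested with camera on log2 CPM (prior count 2, preset correlation 0.01), adjusted over the lists within a comparison, with at least 5 tested members needed. The size contrasts were correlated across genes, with an exact permutation of libraries. A second count of list members used p adjusted over the list alone.

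Lists, contrasts, the tests of genes and lists, the alternatives other than total counts and the rule for naming genes were fixed before the data were examined. Tests of explanations that were chosen later are named as such where they are given. The function lists covered C-type lectin receptors and Syk-Card9 signalling, NF-kB, immediate-early factors, cytokines, ligands tied to Th2 and Th9 priming, chemokines, dendritic cell maturation, MHC class II, type I interferon-stimulated genes, lysosome and phagosome, NADPH oxidase, Nrf2 targets, glycolysis and hypoxia, cholesterol biosynthesis, oxidative phosphorylation, cell cycle, actin and adhesion, eicosanoid synthesis, extracellular proteases, unfolded protein response and alternative activation. Marker lists covered macrophages, dendritic cells, neutrophils, mast cells and basophils, eosinophils, lymphocytes and NK cells, erythroid cells and stromal cells; some genes are in several lists. Named genes, apart from the panel and the cell markers below, had to pass the test at a mean of at least 10 CPM. They could not be predicted or mitochondrial genes. Their groups had to show no overlap (not asked of the difference of size contrasts), which chance gives for 10% of genes with 3 against 3 libraries. Of the genes within these limits, the text draws on the 6 largest and 6 smallest log2 fold changes of each size contrast. It takes 4 and 4 against unstimulated cells and 5 and 5 for the difference. It also draws on the 3 most changed members of the up to 8 function lists with the smallest camera p, and on a panel named whatever its result (Il33, Il1b, Il6, Il12b, Il23a, Il10, Tnf, Tnfsf4, Clec7a and Clec4n, or Il33, Il6, Il1b, Il10 and Tnf against unstimulated cells). The last are the 2 most abundant tested members of marker lists that moved, named whatever their result or level. Of the genes this rule takes, 2 are not reported here.

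A group with no count had its fold computed against a floor of 3 counts over its 3 libraries, and a group with 1 to 3 counts has the ratio with an exact binomial 95% interval. Floors and intervals cover counting error only. Symbols were matched to the GENCODE M21 annotation of GRCm38, 23334 by the current and 643 by an older symbol. Of 147 named genes, 14 share exon bases with another tested gene, which in 10 cases stands at 0.1 or more of the named gene's level. Alternatives were DESeq2 1.42.0, RLE scaling, no filter, a filter of 10 CPM in 3 libraries, replicate number as a block, a fit of only the groups compared, a log2 fold change of at least 1 beside the adjusted p, leaving out each library, and for lists an estimated correlation and fry. Total counts of tested genes as the scale, with no TMM factor, were added after the TMM factors were seen to differ between groups. They shift the median of all genes by -0.12 (yeast), -0.36 (hyphae), -0.03 (6 µm) and -0.09 (25 µm) log2 units against unstimulated cells, and by -0.23, -0.06 and -0.18 for the fungal, bead and difference contrasts.

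The calls were tested on simulated data with 200 changed genes per comparison. Genes changed 4-fold were recovered in 95.9% to 100.0% of cases over the 7 contrasts, 2-fold in 87.5% to 93.6% and 1.25-fold in 42.0% to 66.0%. False calls were 4.17% to 6.63% of calls, and 11.8% for the difference of size contrasts. The simulated changes were few and as often up as down, which suits TMM scaling. In the real comparisons 31.5% (6 µm beads) to 80.7% (hyphae) of genes were called, so these rates need not hold there. The replicate numbers were checked for pairing: residuals of libraries with the same number correlated at r between -0.0420 and 0.0458 over 30 pairs, so they were not used as pairs. Residuals of 8 of the 15 libraries correlated best on average with libraries of their own number, so weak pairing is not excluded. Other splits of the libraries, the matched random lists (10000 per pattern) and the simulated control groups (20) used fixed seeds.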

Results

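Messenger RNA was sequenced from dendritic cells grown from the bone marrow of C57BL/6 mice, 8 to 10 weeks old, in medium with GM-CSF, a growth factor that turns marrow precursors into dendritic cells and macrophage-like cells. At day 8 of culture the cells were left unstimulated or were kept overnight with 1 of 4 stimuli. The first pair of stimuli was Candida albicans, a fungus that grows as small round yeast cells or as long filaments called hyphae, locked in the yeast or in the hyphal form. The second pair was beads of 6 µm or 25 µm diameter coated with β-glucan, a sugar polymer of the fungal cell wall that is bound by the C-type lectin receptor dectin-1 (Clec7a). Each of the 5 groups held 3 libraries, 15 in all. Total counts per library ranged from 17666347 to 23178142, the lowest in an unstimulated and the highest in a 25 µm library. Between 15203 and 15963 genes had at least 1 count per library, and 13059 of 24421 genes were abundant enough to be tested.

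Libraries of the same group lay close together. Across tested genes, their log2 CPM (counts scaled by library size) had a Pearson r of 0.992 to 0.994, where genes are not independent replicates. No 2 of them were alike within sampling noise, since the squared differences of their counts were 2.06 to 5.35 times what counting error alone gives. The labels do not say whether the 3 libraries of a group came from separate cultures or animals, so all p-values measure only the spread between these libraries, which may be technical. Levels are given as mean CPM ± SD (n = 3), and differences as log2 fold change ± SE (n = 3 per group) with the adjusted p of the edgeR quasi-likelihood test after Benjamini-Hochberg adjustment over all tested genes. For gene lists the numbers of members past that test are given. The median log2 fold change of all tested members and the camera p, adjusted over the lists of a comparison, follow in brackets. Camera asks whether a list moved more than other genes. Where no second number follows, the count adjusted over the list alone was the same. Members with 0 counts in a group are set at the bound that the floor gives where a second median is named.

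**Figure D1:**
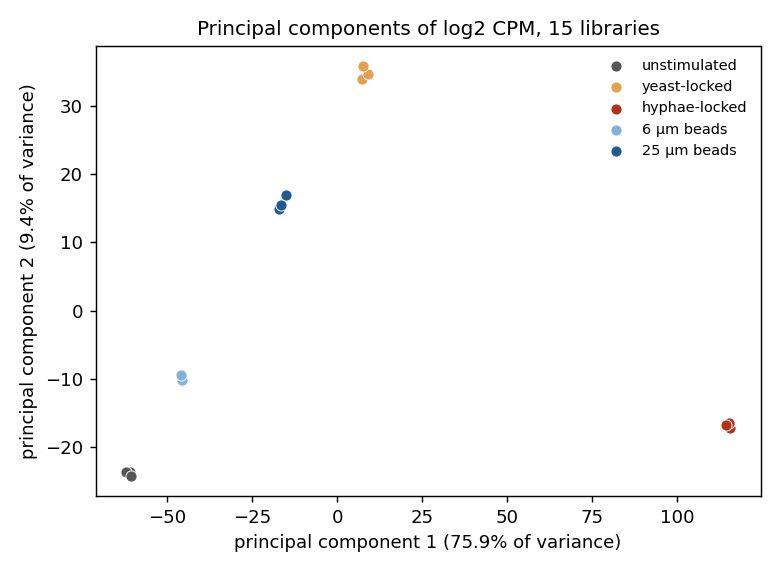
Principal components of log2 CPM of the 15 libraries, 1 point per library coloured by group; component 1 (horizontal, 75.9% of variance) runs from unstimulated libraries near -62.1 to hyphae libraries near 116, and component 2 (vertical) holds 9.39%. Libraries of 1 group overlap or nearly so, and the 6 µm bead libraries lie nearest to the unstimulated ones.

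The title of the series concerns pathogen size, the C-type lectin receptor pathway of dendritic cells and the Th9 cells they prime. The fungal pair addresses this with the larger filaments against the smaller round cells. With hyphae-locked instead of yeast-locked C. albicans, the dendritic cells held far more mRNA of inflammatory cytokines, of type I interferon-stimulated genes and of genes for glycolysis and the response to low oxygen, and less mRNA of cell cycle and MHC class II genes. The camera test of the interferon list did not pass with an estimated correlation (adjusted p = 0.0656). Il33, an alarmin cytokine of the IL-1 family, rose 46.9-fold, from 2.67 ± 0.650 to 125 ± 12.1 CPM (log2 fold change 5.55 ± 0.11, adjusted p = 7.13e-34); unstimulated cells had 1.03 ± 0.265 CPM. Tnf rose 11.7-fold to 1144 ± 19.1 CPM and Il1b 7.45-fold to 1096 ± 20.8 CPM. Top2a, a DNA topoisomerase of dividing cells, was 8.58-fold lower, at 6.55 ± 0.980 against 56.3 ± 4.45 CPM, and H2-DMa, which loads peptides onto MHC class II, was 3.14-fold lower, at 37.4 ± 2.51 against 117 ± 1.13 CPM.

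Of 21 tested inflammatory and T cell-instructing cytokines, 20 rose and 0 fell (median 2.74, camera adjusted p = 1.96e-10). Csf3, which encodes the granulocyte growth factor G-CSF, rose by 9.03 ± 0.13 log2 units and Il10, an anti-inflammatory cytokine, by 8.86 ± 0.20, from 0.125 ± 0.115 to 60.1 ± 2.96 CPM. Without yeast library 1 the Il10 value was 9.62 and without yeast library 3 it was 8.26. Il6 rose by 2.99 ± 0.08, Il12b by 2.00 ± 0.06 and Il23a by 4.72 ± 0.43, the last reaching 5.06 ± 1.19 CPM and taking the value 5.71 without yeast library 2. Among 18 ligands tied to Th2 and Th9 priming, a list that shares Il1a and Il1b with the cytokines, 10 rose and 4 fell (median 1.17, camera adjusted p = 0.00878). Tnfsf4, the OX40 ligand, rose by 1.51 ± 0.05 to 178 ± 2.41 CPM. For chemokines the numbers were 14 higher and 4 lower of 20 (median 2.17, camera adjusted p = 4.15e-04, adjusted p = 0.0656 with an estimated correlation).

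All 31 tested type I interferon-stimulated genes were higher with hyphae (median 1.97, camera adjusted p = 3.63e-17, adjusted p = 0.0656 with an estimated correlation). Rsad2, the antiviral enzyme viperin, rose by 5.19 ± 0.08 to 4519 ± 106 CPM, Cmpk2 by 4.34 ± 0.06 and Ifit1, which has close paralogs, by 4.27 ± 0.09. In the glycolysis and hypoxia list 23 of 24 members rose (median 1.36, camera adjusted p = 5.22e-13), with Egln3, an oxygen-sensing prolyl hydroxylase (3.96 ± 0.07), the growth factor gene Vegfa (3.54 ± 0.04) and Ankrd37 (2.53 ± 0.14). Immediate-early, AP-1, Egr and Nr4a factors gave 22 higher and 2 lower of 25 (median 1.2504, mean 1.40, camera adjusted p = 1.33e-07). The MAP kinase phosphatases Dusp5 and Dusp1 rose by 2.43 ± 0.04 and 2.24 ± 0.05, and the stress factor Atf3 by 2.02 ± 0.03. NF-kB subunits and feedback targets gave 14 higher and 4 lower of 19 (median 0.32, camera adjusted p = 0.00534, adjusted p = 0.244 with an estimated correlation). With total counts as the scale they gave 9 higher and 7 lower (median 0.08), so the size of this rise depends on the scale.

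Of the lists that were lower, the cell cycle had the smallest camera p, with 24 of 26 members lower and 1 higher (median -1.87, camera adjusted p = 1.13e-11). Besides Top2a (-3.10 ± 0.09), the spindle checkpoint gene Bub1b fell by 2.58 ± 0.09 and Rrm2, a subunit of ribonucleotide reductase, by 2.48 ± 0.10. All 14 MHC class II presentation genes were lower (median -1.19, camera adjusted p = 2.38e-08), among them H2-DMa (-1.65 ± 0.05), H2-DMb2 (-2.11 ± 0.08) and Ciita (-1.87 ± 0.06), the transactivator of MHC class II genes. Oxidative phosphorylation had 20 of 22 members lower and 1 higher (median -0.43, camera adjusted p = 1.14e-05), including Ndufb5 (-0.86 ± 0.06) and Ndufa10 (-0.63 ± 0.05) of respiratory complex I. In cholesterol biosynthesis 18 of 22 were lower and 2 higher (median -0.72, camera adjusted p = 5.58e-06, adjusted p = 0.0567 with an estimated correlation), with Idi1 at -1.84 ± 0.06.

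Receptors and adaptors of the C-type lectin pathway did not pass as a list, with 7 of 24 higher and 14 lower (median -0.16, camera adjusted p = 0.146). With total counts as the scale the list did pass, with 5 higher and 16 lower (median -0.39, camera adjusted p = 0.0480), so this call depends on the scale. Clec7a stood at 2452 ± 31.5 CPM with hyphae, 2390.1 ± 88.9 with yeast and 822 ± 16.8 in unstimulated cells. Its hyphae against yeast value (0.04 ± 0.03, adjusted p = 0.316) did not pass, and with total counts as the scale it was -0.20 (adjusted p = 9.67e-07). Clec4n, the gene of dectin-2, fell by 1.17 ± 0.03. Unfolded protein and integrated stress response genes went both ways, 10 higher and 8 lower of 18 (median 0.39, camera adjusted p = 0.553). With these, 12 tested lists did not pass with TMM, at camera adjusted p from 0.126 to 0.892.

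Over all genes, 9541 of 13059 differed between hyphae and yeast, 4757 genes higher and 4784 lower, and 2878 of them by at least a log2 fold change of 1. Among called genes with a mean of at least 10 CPM over the 2 groups, the largest increases were in Ifi202b, Csf3, Il10, Bcat1 (6.87 ± 0.14), an enzyme of branched-chain amino acid breakdown, Edn1 (6.15 ± 0.05), the endothelin precursor, and Clic5 (6.04 ± 0.20). Ifi202b, whose paralogs make it uncertain, had 2 counts in the yeast libraries together, and the ratio of its counts was 1645 (95% counting interval 455 to 13591). Its fitted log2 value was 10.43, and 13.01 without yeast library 1. Under the same limit, which leaves out Ccna2 (-3.87) and other cell cycle genes with low levels, the largest decreases were in Adam23 (-3.92 ± 0.14), Prg2 (-3.65 ± 0.17), Nup210 (-3.62 ± 0.10), Hepacam2 (-3.55 ± 0.11), Asb2 (-3.40 ± 0.08) and Apol7c (-3.26 ± 0.10), the last uncertain because of its paralogs. Cell type markers moved as well: 13 of 16 macrophage markers were lower and 2 higher (median -0.74, camera adjusted p = 7.48e-04), and 11 of 15 dendritic cell markers were lower and 3 higher (median -0.52, camera adjusted p = 0.00878, adjusted p = 0.0552 with total counts as the scale). Eosinophil markers gave 7 lower of 8 (median -2.56, camera adjusted p = 0.00793, adjusted p = 0.0524 with an estimated correlation). Neutrophil markers gave 9 lower and 1 higher of 13 (median -1.45, camera adjusted p = 0.0149, adjusted p = 0.0862 with an estimated correlation and adjusted p = 0.0754 with total counts as the scale). 72 of 83 tested ribosomal protein genes were lower (median -0.40). All 85 ribosomal protein genes of the table, tested or not, took 1.54% ± 0.0622 of counts with hyphae and 2.37% ± 0.0416 with yeast. Later shares of counts for ribosomal protein genes cover these 85 as well. With total counts as the scale, an alternative added after the data were seen, the split was 9851 genes, 3186 higher and 6665 lower.

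**Figure D2:**
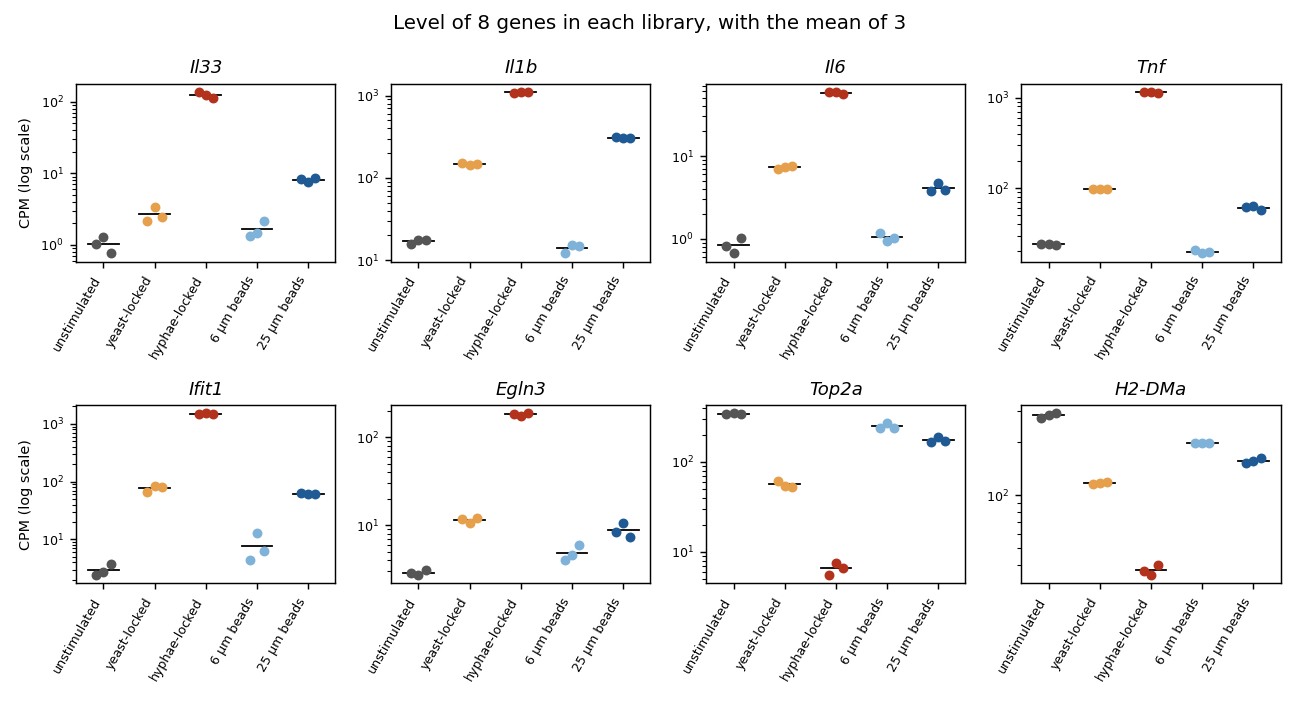
CPM on a log scale of 8 genes in each of the 15 libraries (1 point per library, line at the mean of 3). Il33, Il1b, Il6, Tnf, Ifit1 and Egln3 are highest with hyphae-locked C. albicans, such as Tnf at 1144 CPM, where Top2a (6.55 CPM) and H2-DMa (37.4 CPM) are lowest.

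The bead pair addresses size with a β-glucan coat on both beads. Beads of 25 µm, compared with 6 µm, raised interferon-stimulated genes, NF-kB feedback targets, chemokines and cytokines. Cholesterol biosynthesis and lysosomal genes stood lower with 25 µm than with 6 µm beads. Il1b rose 21.9-fold, from 14.1 ± 1.73 to 308 ± 8.10 CPM (log2 fold change 4.45 ± 0.05, adjusted p = 9.84e-40), and unstimulated cells had 17.1 ± 1.11 CPM. Il33 rose 4.85-fold, from 1.67 ± 0.452 to 8.12 ± 0.434 CPM (2.28 ± 0.16, adjusted p = 9.96e-15). Irf7, a transcription factor that amplifies the interferon response, rose 16.2-fold to 185 ± 4.39 CPM. A log2 value of at least 1 was reached by 743 genes, against 2878 between the fungal forms.

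Of 31 interferon-stimulated genes 30 rose (median 1.98, or 1.94 with 0 counts at their bound, camera adjusted p = 2.18e-40); besides Irf7 (4.02 ± 0.07), Ifi44 rose by 4.19 ± 0.11 and Oasl1, which has a close paralog, by 4.04 ± 0.10. All 19 NF-kB subunits and feedback targets rose (median 0.94, camera adjusted p = 4.36e-24), with Tnfaip3, the inhibitor A20, at 1.56 ± 0.04, Nfkbia at 1.36 ± 0.04 and Nfkbie at 1.30 ± 0.05. Dendritic cell maturation genes gave 20 higher of 22 (median 0.79, camera adjusted p = 3.05e-19), among them the co-stimulatory receptor Cd40 (2.04 ± 0.08) and the chemokine Ccl22 (1.61 ± 0.04). Chemokines gave 17 higher and 1 lower of 20 (median 1.4998, mean 1.81, camera adjusted p = 8.02e-18), with the neutrophil attractants Cxcl3 (3.69 ± 0.05) and Cxcl2 (2.75 ± 0.07). Cytokines gave 16 higher of 21 (median 1.51, or 0.85 with 0 counts at their bound, camera adjusted p = 4.27e-13), with Inhba, a subunit of activins, at 2.34 ± 0.05 and Il1a at 2.26 ± 0.04. Ligands tied to Th2 and Th9 priming gave 12 higher of 18 (median 1.17, or 0.80 with 0 counts at their bound, camera adjusted p = 1.90e-11, 13 higher and 0 lower adjusted over the list alone), including Tnfsf15 (2.61 ± 0.06).

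The glycolysis and hypoxia list had 21 of 24 members higher (median 0.40, camera adjusted p = 5.07e-13), with the glucose transporter Slc2a1 at 0.91 ± 0.04 and Hif1a at 0.60 ± 0.03. Extracellular proteases gave 12 higher and 3 lower of 17 (median 0.62, camera adjusted p = 5.22e-08). Immediate-early factors gave 16 higher and 1 lower of 25 (median 0.42, camera adjusted p = 1.49e-07, 18 higher and 2 lower adjusted over the list alone). Actin and adhesion genes gave 19 higher and 2 lower of 26 (median 0.15, camera adjusted p = 4.88e-06, adjusted p = 0.0658 with an estimated correlation, 19 higher and 3 lower adjusted over the list alone). Nrf2 targets gave 11 higher and 3 lower of 20 (median 0.18, camera adjusted p = 6.88e-04, 12 higher and 4 lower adjusted over the list alone). NADPH oxidase genes gave 5 higher of 9 (median 0.11, camera adjusted p = 0.00930), but 2 higher and 1 lower with total counts as the scale (median 0.05). Cholesterol biosynthesis fell in 21 of 22 genes (median -0.51, camera adjusted p = 1.90e-11), such as Sqle (-0.70 ± 0.04) and Fdps (-0.69 ± 0.05). Lysosome and phagosome genes gave 23 lower and 5 higher of 30 (median -0.25, camera adjusted p = 5.22e-08). Against unstimulated cells these genes gave 22 higher and 0 lower with 6 µm beads (median 0.17). With 25 µm beads they gave 12 higher and 12 lower (median -0.05), so the contrast reflects mostly a rise with 6 µm beads. MHC class II genes gave 7 lower and 1 higher of 14 (median -0.19, camera adjusted p = 0.00568). Cell cycle genes gave 21 lower and 1 higher of 26 (median -0.32, camera adjusted p = 4.14e-05, adjusted p = 0.131 with an estimated correlation, 1 higher and 22 lower adjusted over the list alone).

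C-type lectin receptors and Syk-Card9 signalling genes gave 16 higher and 6 lower of 24 (median 0.21, camera adjusted p = 2.66e-05), where the mean of -0.04 has the other sign. Clec7a rose by 0.58 ± 0.03, from 1236 ± 72.2 to 1847 ± 10.3 CPM, and Clec4n by 0.20 ± 0.03. Among other cytokines, Tnf rose by 1.62 ± 0.05, Il6 by 1.97 ± 0.17, Tnfsf4 by 0.80 ± 0.05 and Il12b by 0.82 ± 0.09. Il23a had no count with 6 µm beads and was at least 3.82-fold higher with 25 µm beads (adjusted p = 0.0110, or 0.121 without 25 µm library 3). Without that library 3 counts remain, which is the floor, so the fold rests on it. Il10 lay at or under the floor of 3 counts per group with both beads, so no fold is given. 10 tested lists did not pass, at camera adjusted p from 0.263 to 0.909.

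Over all genes, 5515 differed between the bead sizes, 2601 genes higher and 2914 lower. Edn1 (4.23 ± 0.10) and Slfn4 (4.22 ± 0.11), the latter uncertain because of its paralogs, were among the largest increases with Il1b and the interferon genes at a mean of at least 10 CPM. Under the same limit of 10 CPM the largest decreases were in Slc36a2 (-2.43 ± 0.11), Fabp4 (-1.97 ± 0.10), a fatty acid-binding protein, Klk1b11 (-1.81 ± 0.09) and Rnase2a (-1.77 ± 0.11), these last uncertain for the same reason, Mamdc2 (-1.76 ± 0.07) and Fcrls (-1.64 ± 0.08). No cell marker list passed; of 16 macrophage markers 6 were higher and 10 lower (median -0.20, camera adjusted p = 0.322), with Lyz2 at -0.14 ± 0.03 and Csf1r at 0.25 ± 0.03. 36 of 83 ribosomal protein genes were lower (median -0.07), with 2.94% ± 0.0674 of counts for 25 µm and 3.27% ± 0.0535 for 6 µm beads. With total counts as the scale the split was 6125 genes, 2114 higher and 4011 lower.

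Whether the fungal and the bead contrast moved the same genes was examined across genes, since the 2 share no library. Hyphae differ from yeast in form as well as size, so what the contrasts share is not shown to come from size. Interferon-stimulated genes were higher with the larger particle in both, 31 of 31 for the fungal forms and 30 of 31 for the beads, as were cytokines (20 and 16 of 21) and glycolysis and hypoxia genes (23 and 21 of 24). Cholesterol biosynthesis genes were lower in both (18 and 21 of 22). For the fungal pair the camera tests of the interferon and cholesterol lists did not pass with an estimated correlation (adjusted p = 0.0656 and 0.0567). In all, 3241 genes were called in the same direction in both contrasts, 1534 higher and 1707 lower with the larger particle. Independent lists of these lengths would share 2015 genes, 947 higher and 1068 lower. A further 1336 genes were called in opposite directions, where independent lists would give 2014. With total counts as the scale 3917 genes shared their direction, 1059 higher and 2858 lower. Across the 13059 tested genes the 2 contrasts, as differences of mean log2 CPM, correlated at a Pearson r of 0.350 and a Spearman rho of 0.312. Genes are not independent, so libraries were permuted: among 100 splits of the 6 fungal and 6 bead libraries none but the real one gave as large an absolute r (two-sided exact permutation p = 0.010, the smallest possible), and the highest of the others was 0.316. The other splits mix 1 or both pairs of groups 2 to 1 and so keep part of each group difference, which lets their r come close to the real one, and this p is no test of whether the contrasts share genes. In a test chosen later, the bead contrast correlated at a higher Pearson r, 0.548, with yeast against unstimulated cells. What the fungal and the bead contrast share is thus not shown to be particular to larger against smaller particles.

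**Figure D3:**
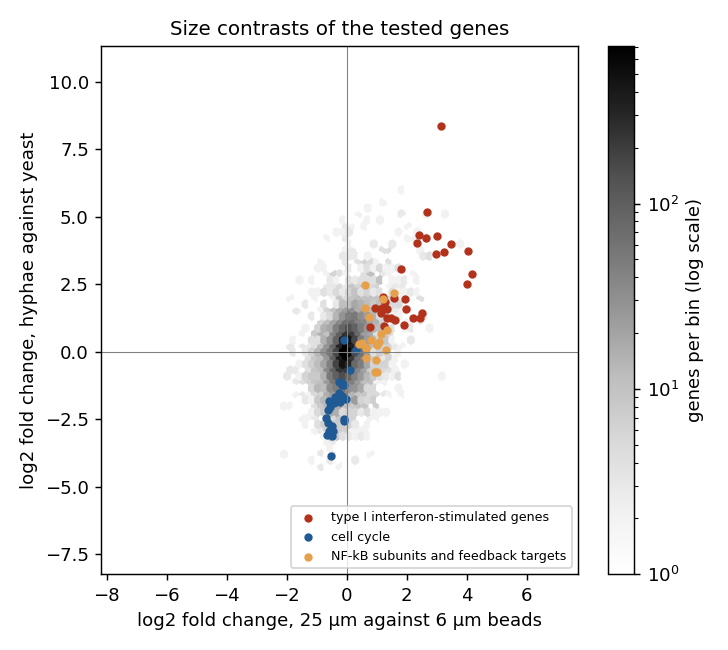
Log2 fold change of hyphae against yeast (vertical) over that of 25 µm against 6 µm beads (horizontal) for 13059 tested genes, as bins shaded by gene number on a log scale, with 3 gene lists as coloured points. All interferon-stimulated genes lie above 0 on the vertical axis (median 1.97), all NF-kB genes lie right of 0, and the cell cycle genes lie lower on the vertical axis (median -1.87) than they lie left on the horizontal one (median -0.32).

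The contrast of larger with smaller particle also differed between the pairs, tested as hyphae minus yeast less 25 µm minus 6 µm. Cell cycle and MHC class II genes fell far more, and glycolysis and hypoxia genes rose more, from yeast to hyphae than from small to large beads. Vegfa differed by 3.31 ± 0.06 log2 units, with 3.54 for the fungal pair and 0.23 for the beads. Ccna2, the gene of cyclin A, differed by -3.36 ± 0.18 (-3.87 and -0.51). Fscn1, an actin-bundling protein of mature dendritic cells, went opposite ways, -1.67 for the fungal pair and 1.11 for the beads (difference -2.78 ± 0.06), as did the adhesion molecule Icam1 (-0.74 and 1.00) and the receptor Tlr2 (-1.09 and 1.14).

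By list, where higher means a more positive effect in the fungal pair, cell cycle gave 1 higher and 25 lower of 26 (median -1.53, camera adjusted p = 5.29e-12). MHC class II presentation gave 0 higher and 14 lower of 14 (median -1.06, camera adjusted p = 1.02e-08). Oxidative phosphorylation gave 1 higher and 20 lower of 22 (median -0.36, camera adjusted p = 4.76e-05). Dendritic cell maturation gave 5 higher and 16 lower of 22 (median -0.98, camera adjusted p = 1.45e-04, adjusted p = 0.183 with an estimated correlation). C-type lectin receptors and Syk-Card9 signalling gave 3 higher and 16 lower of 24 (median -0.29, camera adjusted p = 1.45e-04), with Clec4n at -1.37 ± 0.04 and Clec4e, the gene of Mincle, at -1.31 ± 0.06. NF-kB subunits and feedback targets gave 5 higher and 13 lower of 19 (median -0.49, camera adjusted p = 0.00708, adjusted p = 0.256 with an estimated correlation). Cholesterol biosynthesis gave 4 higher and 12 lower of 22 (median -0.44, camera adjusted p = 0.0221, adjusted p = 0.321 with an estimated correlation). In the other direction glycolysis and hypoxia gave 21 higher and 2 lower of 24 (median 0.85, camera adjusted p = 4.80e-10). Immediate-early factors gave 17 higher and 3 lower of 25 (median 0.87, camera adjusted p = 4.76e-05, 19 higher and 3 lower adjusted over the list alone), with Dusp5 at 2.05 ± 0.07. Cytokines gave 12 higher and 3 lower of 21 (median 1.02, camera adjusted p = 1.78e-04). Lysosome and phagosome gave 17 higher and 8 lower of 30 (median 0.23, camera adjusted p = 0.00991, adjusted p = 0.245 with an estimated correlation and adjusted p = 0.0592 with total counts as the scale). With total counts the split was 13 higher and 11 lower (median 0.05). Interferon-stimulated genes did not differ as a list, at 16 higher and 10 lower of 31 (median 0.27, camera adjusted p = 0.478, 16 higher and 11 lower adjusted over the list alone), and with them 12 tested lists did not pass (camera adjusted p from 0.177 to 0.831).

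Among called genes with a mean of at least 10 CPM over the 4 groups, those with the largest positive difference included Emp1 (4.34 for the fungal pair, -1.28 for the beads), a membrane protein, and Dusp13 (4.87 and -0.66). The most negative were Apol7c (-3.26 and 2.29) and Adgre4 (-3.00 and 1.58), an adhesion receptor of myeloid cells. Macrophage markers gave 2 higher and 11 lower of 16 (median -0.57, camera adjusted p = 0.00245, 3 higher and 11 lower adjusted over the list alone). Dendritic cell markers gave 3 higher and 9 lower of 15 (median -1.05, camera adjusted p = 0.00991). Eosinophil markers gave 1 higher and 6 lower of 8 (median -2.73, camera adjusted p = 0.0213, adjusted p = 0.0931 with an estimated correlation and adjusted p = 0.0592 with total counts as the scale). Neutrophil markers gave 1 higher and 8 lower of 13 (median -1.10, camera adjusted p = 0.0470, adjusted p = 0.185 with an estimated correlation and adjusted p = 0.110 with total counts as the scale). For these the adjusted p lay between 0.0537 and 0.0741 without yeast library 2, hyphae library 2 or 3, 6 µm library 1 or 2, or 25 µm library 1, and was 0.0502 with the replicate number as a block. 65 of 83 ribosomal protein genes were lower (median -0.29). Over all genes 8014 differed, 4011 genes higher and 4003 lower, and 2389 by a log2 value of at least 1; with total counts as the scale the split was 8132 genes, 2791 higher and 5341 lower.

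Each stimulus was then set against unstimulated cells. Yeast-locked C. albicans raised interferon-stimulated, cytokine and oxidative stress genes and lowered cell cycle and cholesterol genes. Nos2, the inducible nitric oxide synthase, rose from 0.432 ± 0.163 to 43.0 ± 0.955 CPM (log2 fold change 6.64 ± 0.12, adjusted p = 2.69e-34). Ptgs2, the inducible cyclooxygenase, rose 47.7-fold to 45.2 ± 1.30 CPM. Cyp26b1, which degrades retinoic acid, rose 31.9-fold. Clec10a, a lectin of alternatively activated cells, was 11.9-fold lower at 5.74 ± 0.557 CPM, and Asgr2 and the mitotic gene Aspm were also among the largest decreases at a mean of at least 10 CPM (-4.21 ± 0.13 and -3.61 ± 0.12).

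With yeast, interferon-stimulated genes gave 29 higher of 31 (median 2.52, camera adjusted p = 1.77e-21), with Ifi44 at 4.84 ± 0.14. NF-kB genes gave 18 higher of 19 (median 0.72, camera adjusted p = 3.52e-11). Dendritic cell maturation gave 21 higher of 22 (median 0.81, camera adjusted p = 2.66e-11), with Cd40 at 2.29 ± 0.08, and Cd274, the gene of PD-L1, at 1.58 ± 0.04. Cytokines gave 16 higher and 1 lower of 21 (median 2.02, or 1.64 with 0 counts at their bound, camera adjusted p = 1.23e-07, 17 higher and 1 lower adjusted over the list alone), with Inhba at 3.96 ± 0.05, Il1b at 3.10 ± 0.05, Il6 at 3.10 ± 0.16 and Tnf at 2.02 ± 0.04. Il33 rose by 1.37 ± 0.24 to 2.67 ± 0.650 CPM. Il10 had no count in unstimulated cells and was at least 2.62-fold higher with yeast (adjusted p = 0.00929, or 0.0611 without yeast library 1). Without that library 3 counts remain, which is the floor, so the fold rests on it. Nrf2 targets gave 15 higher and 4 lower of 20 (median 1.09, camera adjusted p = 4.68e-08), with Nqo1 (2.89 ± 0.05) and Hmox1 (2.42 ± 0.03). Glycolysis and hypoxia gave 20 higher of 24 (median 0.52, camera adjusted p = 2.48e-09). Proteases gave 13 higher and 3 lower of 17 (median 0.73, camera adjusted p = 3.73e-06). Lysosome and phagosome gave 21 higher and 5 lower of 30 (median 0.38, camera adjusted p = 4.70e-06). Ligands tied to Th2 and Th9 priming gave 10 higher and 3 lower of 18 (median 0.86, camera adjusted p = 0.00119).

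Chemokines gave 11 higher and 5 lower of 20 (median 1.13, or 1.06 with 0 counts at their bound, camera adjusted p = 0.00445, adjusted p = 0.125 with an estimated correlation, 12 higher and 5 lower adjusted over the list alone) with yeast. Immediate-early factors gave 14 higher and 4 lower of 25 (median 0.22, camera adjusted p = 0.00962, adjusted p = 0.0666 with an estimated correlation). Cell cycle genes gave 26 lower of 26 (median -2.17, camera adjusted p = 5.34e-21), with Ccnb2 at -3.24 ± 0.10. Cholesterol biosynthesis gave 21 lower of 22 (median -0.66, camera adjusted p = 3.43e-10, 0 higher and 22 lower adjusted over the list alone). MHC class II gave 4 higher and 9 lower of 14 (median -0.37, camera adjusted p = 0.00958, adjusted p = 0.0504 with an estimated correlation). Alternative activation gave 4 higher and 10 lower of 14 (median -1.74, camera adjusted p = 0.00317), the higher members including Irf4 (0.46 ± 0.03). Macrophage markers gave 4 higher and 12 lower of 16 (median -0.85, camera adjusted p = 7.26e-05), with Lyz2 at -0.83 ± 0.03 and Csf1r at 0.34 ± 0.03; 11 lists did not pass (camera adjusted p from 0.0731 to 0.822). 76 of 83 ribosomal protein genes were lower (median -0.61), at 2.37% ± 0.0416 of counts against 3.91% ± 0.0162 in unstimulated cells. In all 8294 genes changed, 4133 genes higher and 4161 lower, with 1934 past a log2 value of 1; total counts as the scale gave 8470 genes, 2991 higher and 5479 lower.

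Hyphae-locked C. albicans changed the most genes of the 4 stimuli, 10544 of 13059, 5245 genes higher and 5299 lower, and 4531 past a log2 value of 1; total counts as the scale gave 10858 genes, 3422 higher and 7436 lower. Cytokine and interferon-stimulated genes rose to high levels while cell cycle genes fell. Ptgs2 rose 1955-fold to 1849.8 ± 45.9 CPM (10.93 ± 0.08, adjusted p = 3.18e-48). Il10, with no count in unstimulated cells, was at least 1279-fold higher, and Ifi202b, also without a count there and uncertain because of its paralogs, at least 1078-fold. Csf3 had 1 count in the unstimulated libraries together and a ratio of counts of 9955 (95% counting interval 1786 to 393250.0); its log2 value was 12.81, and 14.62 without unstimulated library 3. The mitosis and DNA repair genes Fam64a, Cenpf, Neil3 and Kif2c were lower, at -7.87 ± 0.24, -7.50 ± 0.20, -7.11 ± 0.24 and -6.99 ± 0.23. Their hyphae levels were under 0.3 CPM, and leaving out 1 hyphae library moved Fam64a to -8.54 (library 1), Cenpf to -8.66 (library 2), Neil3 to -7.89 or -6.52 (library 1 or 2) and Kif2c to -6.40 or -8.27 (library 1 or 3).

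With hyphae, cytokines gave 20 higher of 21 (median 4.87, camera adjusted p = 1.66e-09); Il33 rose by 6.92 ± 0.12, Il6 by 6.09 ± 0.12, Il1b by 6.00 ± 0.05 and Tnf by 5.57 ± 0.04. Interferon-stimulated genes gave 31 higher of 31 (median 4.54, camera adjusted p = 1.58e-17), with Rsad2 at 9.13 ± 0.11. Ligands tied to Th2 and Th9 priming gave 14 higher and 3 lower of 18 (median 2.42, camera adjusted p = 4.15e-04). Chemokines gave 16 higher and 4 lower of 20 (median 2.99, camera adjusted p = 8.44e-05). Glycolysis and hypoxia gave 23 higher of 24 (median 1.87, camera adjusted p = 5.77e-12), with Egln3 at 5.96 ± 0.09 and Bnip3 at 2.84 ± 0.06. Immediate-early factors gave 23 higher and 2 lower of 25 (median 1.58, camera adjusted p = 4.61e-07), with Dusp4 at 4.44 ± 0.12. NF-kB genes gave 16 higher and 2 lower of 19 (median 1.21, camera adjusted p = 1.50e-06, 16 higher and 3 lower adjusted over the list alone), with Nfkbiz at 3.16 ± 0.08. Proteases gave 13 higher and 4 lower of 17 (median 1.32, camera adjusted p = 0.00200). Nrf2 targets gave 15 higher and 5 lower of 20 (median 1.95, camera adjusted p = 4.15e-04). Dendritic cell maturation gave 15 higher and 4 lower of 22 (median 0.81, camera adjusted p = 0.00200, adjusted p = 0.199 with an estimated correlation, 15 higher and 5 lower adjusted over the list alone). Lysosome and phagosome gave 19 higher and 9 lower of 30 (median 0.43, camera adjusted p = 0.0218, adjusted p = 0.232 with an estimated correlation and adjusted p = 0.0818 with total counts as the scale). With total counts the split was 15 higher and 13 lower (median 0.07).

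Among lists lowered by hyphae, cell cycle gave 26 lower of 26 (median -4.09, camera adjusted p = 1.45e-14), with Ccna2 at -6.80 ± 0.11. MHC class II gave 1 higher and 13 lower of 14 (median -1.67, camera adjusted p = 4.68e-06), with Ciita at -2.24 ± 0.06. Cholesterol biosynthesis gave 22 lower of 22 (median -1.40, camera adjusted p = 3.05e-09). Oxidative phosphorylation gave 1 higher and 18 lower of 22 (median -0.49, camera adjusted p = 3.63e-04, 1 higher and 19 lower adjusted over the list alone). Eicosanoid synthesis gave 3 higher and 10 lower of 14 (median -1.16, camera adjusted p = 0.0271, adjusted p = 0.134 with an estimated correlation and adjusted p = 0.131 with total counts as the scale). The higher members of this list include Ptgs2, whose large rise with hyphae is given above, so the list did not fall as a whole. Macrophage markers gave 2 higher and 14 lower of 16 (median -1.64, camera adjusted p = 9.63e-06), with Lyz2 at -1.53 ± 0.03 and Csf1r at -1.35 ± 0.03. Dendritic cell markers gave 4 higher and 11 lower of 15 (median -1.20, camera adjusted p = 0.0237, adjusted p = 0.105 with total counts as the scale), with Itgax (CD11c) at -0.29 ± 0.03 but Irf4 at 1.80 ± 0.03. Eosinophil markers gave 8 lower of 8 (median -2.88, camera adjusted p = 0.00396), with Prg2 at -3.59 ± 0.17. 8 lists did not pass (camera adjusted p from 0.0565 to 0.850). 76 of 83 ribosomal protein genes were lower (median -1.03), at 1.54% ± 0.0622 of counts against 3.91% ± 0.0162 in unstimulated cells.

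Beads of 6 µm had the mildest effect: 4108 genes changed, 1959 genes higher and 2149 lower, but only 204 past a log2 value of 1, and total counts as the scale gave 4130 genes, 1508 higher and 2622 lower. Oxidative stress and lysosomal genes rose, cell cycle genes and macrophage markers fell, and inflammatory cytokines did not move as a list. Inhba rose 2.89-fold from 25.6 ± 2.56 to 73.8 ± 3.77 CPM (1.53 ± 0.06, adjusted p = 4.09e-22), and Rgs1, a regulator of G-protein signalling, 2.48-fold to 82.1 ± 5.52 CPM. Apoe, the lipid carrier apolipoprotein E, was 2.78-fold lower at 122 ± 10.4 CPM. Slc39a2 (1.31 ± 0.08) and Bhlhe41 (1.24 ± 0.04) were among the largest increases, and Adgre4 (-1.21 ± 0.06) and Mmp9 (-1.20 ± 0.05) among the largest decreases, at a mean of at least 10 CPM.

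With 6 µm beads, Nrf2 targets gave 15 higher and 3 lower of 20 (median 0.30, camera adjusted p = 8.55e-12, 16 higher and 3 lower adjusted over the list alone), with Nqo1 at 0.76 ± 0.06, and Mt2 and Prdx1, which have near-identical copies, at 1.23 ± 0.06 and 1.20 ± 0.04. Lysosome and phagosome gave 22 higher of 30 (median 0.17, camera adjusted p = 3.36e-14), with the protease Ctsk at 1.04 ± 0.07, Gpnmb at 0.71 ± 0.03 and the proton pump subunit Atp6v0d2 at 0.63 ± 0.03. Interferon-stimulated genes gave 24 higher and 2 lower of 31 (median 0.67, camera adjusted p = 4.02e-15, adjusted p = 0.1004 with an estimated correlation, 24 higher and 3 lower adjusted over the list alone), with Oas3 at 1.17 ± 0.06. Glycolysis and hypoxia gave 13 higher and 3 lower of 24 (median 0.12, camera adjusted p = 4.36e-04, adjusted p = 0.245 with an estimated correlation, 14 higher and 3 lower adjusted over the list alone). Proteases gave 10 higher and 3 lower of 17 (median 0.11, camera adjusted p = 0.00332). Cell cycle gave 26 lower of 26 (median -0.48, camera adjusted p = 8.22e-16). Alternative activation gave 2 higher and 10 lower of 14 (median -0.56, camera adjusted p = 4.12e-05), with Retnla at -1.09 ± 0.11 and Mgl2 at -0.89 ± 0.03. MHC class II gave 2 higher and 9 lower of 14 (median -0.30, camera adjusted p = 1.62e-04). Eicosanoid synthesis gave 1 higher and 8 lower of 14 (median -0.25, camera adjusted p = 9.23e-04, 1 higher and 9 lower adjusted over the list alone). NF-kB genes gave 1 higher and 8 lower of 19 (median -0.05, camera adjusted p = 0.0231, adjusted p = 0.393 with an estimated correlation, 1 higher and 9 lower adjusted over the list alone), with adjusted p = 0.117 without unstimulated library 1.

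In the cytokine panel with 6 µm beads, Il1b fell by 0.29 ± 0.07 and Tnf by 0.27 ± 0.06, while Il6 (0.31 ± 0.25, adjusted p = 0.399) did not pass and Il10 lay at or under the floor in both groups. Il33 passed (0.71 ± 0.26, adjusted p = 0.0341), with 1.67 ± 0.452 CPM. The adjusted p was 0.0653, 0.195 and 0.254 without unstimulated library 1, unstimulated library 3 or 6 µm library 3, and 0.0765 in a fit of these groups alone. Macrophage markers gave 13 lower of 16 (median -0.31, camera adjusted p = 3.07e-11), with Lyz2 at -0.25 ± 0.03. Dendritic cell markers gave 2 higher and 9 lower of 15 (median -0.31, camera adjusted p = 0.0253, adjusted p = 0.0697 with an estimated correlation, 3 higher and 10 lower adjusted over the list alone), with adjusted p = 0.0528 without 6 µm library 1. Eosinophil markers gave 6 lower of 8 (median -0.61, camera adjusted p = 0.0231, adjusted p = 0.0921 with an estimated correlation), with adjusted p = 0.0599 without unstimulated library 1 and 0.0528 without 6 µm library 1. 14 lists did not pass (camera adjusted p from 0.0687 to 0.998). 74 of 83 ribosomal protein genes were lower (median -0.23), at 3.27% ± 0.0535 of counts.

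Beads of 25 µm changed 6671 genes, 3133 genes higher and 3538 lower, and 1080 past a log2 value of 1; total counts as the scale gave 7375 genes, 2328 higher and 5047 lower. Interferon-stimulated, NF-kB, chemokine and cytokine genes rose and cell cycle genes fell. Ifi44 rose 43.0-fold from 0.786 ± 0.109 CPM (5.43 ± 0.13, adjusted p = 2.26e-30). Irf7 rose 31.6-fold to 185 ± 4.39 CPM and Edn1 21.8-fold to 25.3 ± 1.13 CPM. Il33 rose 7.93-fold to 8.12 ± 0.434 CPM and Il1b 17.9-fold to 308 ± 8.10 CPM. Fcrls was 6.24-fold lower and the integrin gene Itgb7 5.57-fold.

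With 25 µm beads, interferon-stimulated genes gave 30 higher of 31 (median 2.59, camera adjusted p = 3.84e-35). NF-kB genes gave 19 higher of 19 (median 0.80, camera adjusted p = 5.89e-17), with Traf1 at 1.27 ± 0.05. Dendritic cell maturation gave 20 higher of 22 (median 0.86, camera adjusted p = 2.65e-16), with Cd200 at 1.42 ± 0.06. Chemokines gave 17 higher of 20 (median 1.73, camera adjusted p = 8.71e-14, 18 higher and 0 lower adjusted over the list alone), with Cxcl3 at 3.37 ± 0.05. Cytokines gave 14 higher and 1 lower of 21 (median 1.344 with 0 counts not set at their bound, camera adjusted p = 1.60e-09), with Il1a at 2.49 ± 0.04, Il6 at 2.28 ± 0.18 and Tnf at 1.34 ± 0.05. Ligands tied to Th2 and Th9 priming gave 12 higher and 2 lower of 18 (median 1.04, camera adjusted p = 5.19e-09). Glycolysis and hypoxia gave 22 higher of 24 (median 0.46, camera adjusted p = 3.80e-14, 23 higher and 0 lower adjusted over the list alone), with Slc16a3, a lactate transporter, at 0.86 ± 0.05. Nrf2 targets gave 17 higher and 2 lower of 20 (median 0.49, camera adjusted p = 3.72e-09), with the cystine transporter Slc7a11 at 1.61 ± 0.04. Proteases gave 13 higher and 3 lower of 17 (median 0.73, camera adjusted p = 3.72e-09). Immediate-early factors gave 13 higher and 1 lower of 25 (median 0.26, camera adjusted p = 9.72e-05). Actin and adhesion gave 17 higher and 3 lower of 26 (median 0.14, camera adjusted p = 4.67e-04, adjusted p = 0.144 with an estimated correlation, 19 higher and 4 lower adjusted over the list alone). C-type lectin receptors and Syk-Card9 signalling gave 15 higher and 7 lower of 24 (median 0.24, camera adjusted p = 4.92e-04), where the mean of -0.09 has the other sign.

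Lists lowered by 25 µm beads were cell cycle, with 25 lower of 26 (median -0.75, camera adjusted p = 1.96e-13) and Birc5 at -1.30 ± 0.08. Cholesterol biosynthesis gave 18 lower of 22 (median -0.40, camera adjusted p = 3.26e-08, 0 higher and 19 lower adjusted over the list alone). MHC class II gave 3 higher and 10 lower of 14 (median -0.44, camera adjusted p = 4.61e-05). Eicosanoid synthesis gave 2 higher and 7 lower of 14 (median -0.25, camera adjusted p = 0.0171, adjusted p = 0.105 with an estimated correlation, 3 higher and 8 lower adjusted over the list alone). Macrophage markers gave 5 higher and 10 lower of 16 (median -0.39, camera adjusted p = 0.00303). 10 lists did not pass (camera adjusted p from 0.0711 to 0.942). 73 of 83 ribosomal protein genes were lower (median -0.34), at 2.94% ± 0.0674 of counts.

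**Figure D4:**
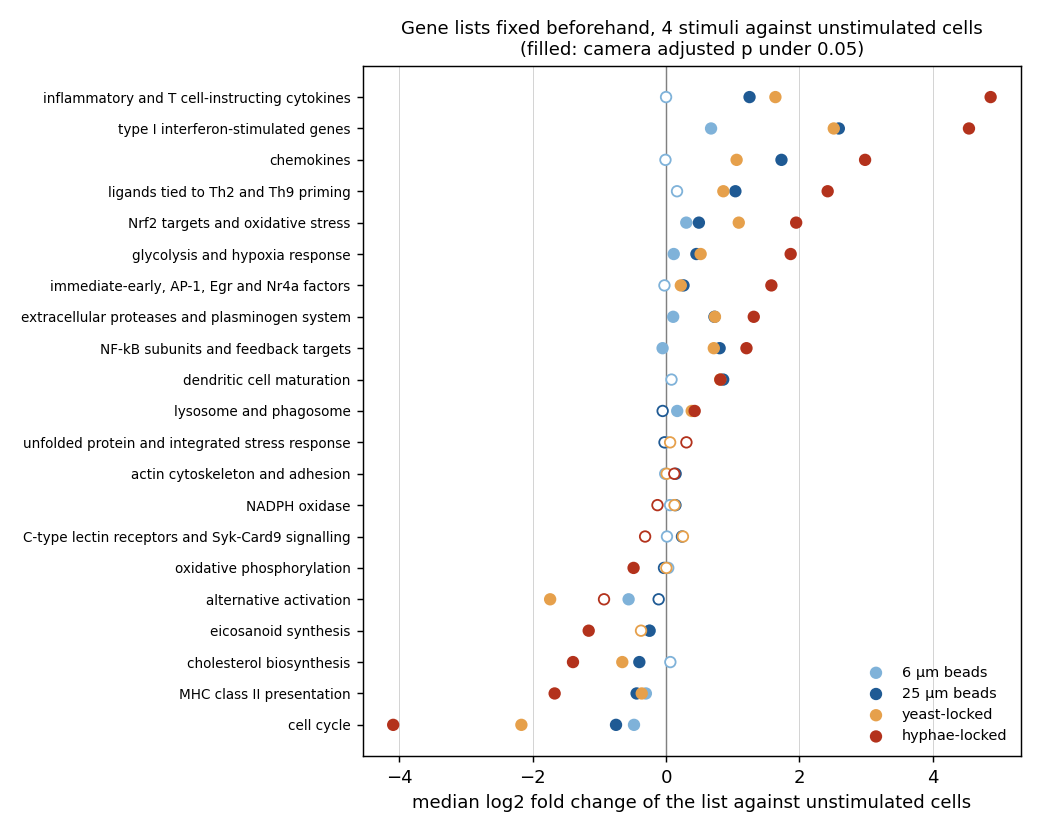
Median log2 fold change against unstimulated cells (horizontal) of 21 function lists (vertical) for the 4 stimuli, with members at 0 counts set at their bound; filled points have a camera adjusted p under 0.05. The median of the cytokine list is 4.87 with hyphae and 1.64 with yeast, and that of the cell cycle list is -4.09 with hyphae and -0.48 with 6 µm beads.

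All 4 stimuli moved 2458 genes in the same direction, 1091 higher and 1367 lower; total counts as the scale gave 2610, 688 higher and 1922 lower. Cell cycle genes fell with each, 26 with yeast, 26 with hyphae, 26 with 6 µm and 25 with 25 µm beads of 26, and Nrf2 targets rose, 15, 15, 15 and 17 of 20 in the same order. The lists of macrophage markers and MHC class II genes moved down with each, the MHC list with yeast only at the preset correlation (adjusted p = 0.0504 with an estimated correlation). Independent lists of the 4 lengths would share 135 genes, 59.7 higher and 75.3 lower. In 20 simulations of unchanged groups against the same controls 0 genes were shared at most, but with no effect hardly any gene passes, so this does not measure what shared controls add to real effects. Part of the excess may come from the shared controls, since 3 control libraries cannot be split.

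Lists of other cell types were examined too. None of 11 erythroid markers was abundant enough to be tested, and 2 of 15 lymphocyte and NK cell markers were, too few for a list test; 2 of these fell with hyphae. Mast cell and basophil markers did not pass in any comparison; with hyphae against unstimulated cells 2 were higher and 3 lower of 5 (median -0.81, camera adjusted p = 0.850), where the mean of 0.61 has the other sign. Of these, Gata2 rose by 2.69 ± 0.08 and Kit fell by 1.12 ± 0.10. Stromal cell markers did not pass in any comparison either; with hyphae 3 were lower and 1 higher of 8 (median -0.55, camera adjusted p = 0.597), and Acta2 stood at 4.35 ± 0.544 CPM in unstimulated cells. The neutrophil marker Mmp8 stood at 911 ± 7.49 CPM in unstimulated cells, 1796 ± 39.2 with yeast, 1327 ± 50.9 with hyphae, 1061 ± 79.3 with 6 µm and 774 ± 16.0 with 25 µm beads. The macrophage gene Lyz2 stood at 25086 ± 423 CPM in unstimulated cells and 8694 ± 82.8 with hyphae.

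The files name genes by symbol and give no coordinates. On GRCm38, the build named in the submitters' processing notes, the genes of the plot of CPM by library lie within these bounds of the GENCODE M21 annotation, 1-based and from the first to the last base of the gene: Il33 (chromosome 19, 29925114 to 29960718, plus strand), Il1b (chromosome 2, 129364570 to 129371139, minus strand), Il6 (chromosome 5, 30013114 to 30019981, plus strand), Tnf (chromosome 17, 35199381 to 35202007, minus strand), Ifit1 (chromosome 19, 34640871 to 34650009, plus strand), Egln3 (chromosome 12, 54178981 to 54203860, minus strand), Top2a (chromosome 11, 98992943 to 99024189, minus strand) and H2-DMa (chromosome 17, 34119541 to 34139101, plus strand). Counts were given per gene, so which exons or untranslated regions held the reads was not analysed here. Some genes are uncertain because their reads can be shared with near-identical copies and the treatment of such reads is not given in the sources used here: Ifi202b, Ifit1, Oasl1, Ly6i, Klk1b11, Rnase2a, Apol7c, Slfn4, Mt2, Prdx1 and the ribosomal protein genes. Others share exon bases with a neighbouring gene. Most of these neighbours lie on the opposite strand, and without a stated strand setting the reads cannot be separated there. Slc39a2 and Mettl17 lie on the same strand, where no strand setting separates them. H2-DMa shares 10.4% of its exon bases with Brd2, Ccna2 12.5% with Exosc9 and Ndufb5 12.3% with Mrpl47, while Ankrd37, Cdc20, Ciita, Cyp51, Dusp1, Irf7 and Slc39a2 share under 5% with a gene at 0.1 or more of their level.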

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

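The tests in this part were planned, except the scaling test of the cell cycle list, which was chosen only after the result was seen. A test of the difference itself set these results apart: 8014 genes had a contrast of larger with smaller particle that differed between the fungal forms (hyphae against yeast, which differ in form too) and the beads (25 µm against 6 µm). Each gene is given as the difference in log2 units ± SE, with the fungal and the bead value in brackets. The bead value itself did not pass for Bub1b (adjusted p = 0.127), Sdhb (0.298), Ndufa10 (0.424) and Ier3 (0.534). Nor did it for Adgra3 (0.217), Wfdc21 (0.684), Acta2 (0.270), Col1a2 (0.0816) and Il10 (0.689). For Col1a2 the fungal value did not pass either (adjusted p = 0.266). Of the cell cycle, Ccna2 -3.36 ± 0.18 (-3.87 and -0.51), Top2a -2.59 ± 0.11 (-3.10 and -0.51) and Bub1b -2.48 ± 0.10 (-2.58 and -0.10) fell more in the fungal pair. MHC class II genes did so too, with H2-DMb2 -1.83 ± 0.10 (-2.11 and -0.27), Ciita -1.61 ± 0.08 (-1.87 and -0.26) and H2-DMa -1.32 ± 0.06 (-1.65 and -0.33), as did the respiratory chain genes Ndufb5 -0.72 ± 0.08 (-0.86 and -0.14), Sdhb -0.68 ± 0.06 (-0.62 and 0.05) and Ndufa10 -0.58 ± 0.06 (-0.63 and -0.05). Hypoxia genes rose more in the fungal pair, with Vegfa 3.31 ± 0.06 (3.54 and 0.23), Egln3 3.11 ± 0.16 (3.96 and 0.85) and Bnip3 1.81 ± 0.08 (1.99 and 0.18), as did Dusp5 2.05 ± 0.07 (2.43 and 0.37), Ier3 1.95 ± 0.07 (1.99 and 0.04) and Atf3 1.69 ± 0.05 (2.02 and 0.33), and the cytokine gene Lif 1.95 ± 0.21 (2.74 and 0.79).

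Maturation and receptor genes parted in direction or size, with Fscn1 -2.78 ± 0.06 (-1.67 and 1.11), Slamf1 2.17 ± 0.23 (3.00 and 0.83), Icam1 -1.74 ± 0.05 (-0.74 and 1.00), Tlr2 -2.23 ± 0.06 (-1.09 and 1.14), Clec4n -1.37 ± 0.04 (-1.17 and 0.20) and Clec4e -1.31 ± 0.06 (0.79 and 2.10). At a mean of at least 10 CPM over the 4 groups the most positive called differences were Il10, Emp1 5.62 ± 0.10 (4.34 and -1.28), Dusp13 5.53 ± 0.21 (4.87 and -0.66), Bcat1 5.45 ± 0.49 (6.87 and 1.42) and Adgra3 4.82 ± 0.35 (5.24 and 0.42), where Bcat1 was 4.75 without 6 µm library 3. The most negative were Ly6i -4.07 ± 0.10 (-1.71 and 2.36), Prg2 -4.23 ± 0.21 (-3.65 and 0.59), Adam23 -4.27 ± 0.17 (-3.92 and 0.35), Adgre4 -4.58 ± 0.11 (-3.00 and 1.58) and Apol7c -5.55 ± 0.13 (-3.26 and 2.29). Il10 at 8.03 is a fitted value that depends on the prior count, since both bead groups lay at or under the floor, with adjusted p = 0.959 at 6.22 without 6 µm library 3; it was 10.66 without 25 µm library 1, 7.43 without 25 µm library 3, 8.79 without yeast library 1 and 7.44 without yeast library 3. Csf3 at 4.10 rests on 2 counts with 6 µm beads, and was 1.503 with adjusted p = 0.732 without 6 µm library 2.

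Most of the named cell markers differed as well, with Lyz2 -0.56 ± 0.04 (-0.70 and -0.14) and Csf1r -1.94 ± 0.05 (-1.69 and 0.25) for macrophages, Itgax -0.78 ± 0.04 (-0.47 and 0.31) and Irf4 0.88 ± 0.05 (1.33 and 0.45) for dendritic cells, Wfdc21 -1.10 ± 0.08 (-1.13 and -0.03) for neutrophils, Gata2 1.40 ± 0.12 (2.00 and 0.60) and Kit -1.40 ± 0.12 (-2.00 and -0.60) for mast cells and basophils, and Acta2 -0.93 ± 0.25 (-1.16 and -0.23) for stromal cells. The other neutrophil marker, Mmp8, did not pass (0.02 ± 0.05 (-0.44 and -0.46), adjusted p = 0.780), nor did Siglecf for eosinophils (0.10 ± 0.08 (-0.20 and -0.31), adjusted p = 0.2995). The stromal gene Col1a2 passed at -0.67 (-0.27 and 0.41) with adjusted p = 0.0401, although neither bracketed value passed by itself. Its adjusted p was 0.0796 with DESeq2, 0.111 without yeast library 2, 0.102 and 0.0633 without hyphae library 1 or 3, 0.0580 without 6 µm library 1, and 0.0969 and 0.0891 without 25 µm library 2 or 3.

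Other splits of the libraries were run for this count. Of 100 splits drawn from 200, 2 gave at least 8014 genes, the real one included, a share under 0.05. The other was the highest, at 8979 genes, and keeps both real pairs with the bead sizes exchanged, which adds the effects instead of subtracting them. Splits that kept only the fungal groups still reached 7302 genes, those that kept only the bead groups 454, and 77 splits that kept neither gave 0, where mixed groups add to the spread. Most of the count can thus come from hyphae against yeast alone, and the order of the splits follows which real groups stay intact, so this share alone does not firmly exclude chance. That the pairs differ rests on the test of the difference.

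The lower cell cycle list with hyphae than with yeast was weighed against technical explanations. A bias by exonic length, the union of a gene's annotated exons, is argued against. Medians of 10000 random lists matched in exonic length and level lay around 0.00486, with a 1st percentile of -0.30, and the list lay at -1.87. The length of the transcripts present was not matched. Scaling as the whole cause is argued against too, since it would move all genes alike. The list's median less that of the other tested genes was -1.87, from -2.09 to -1.72 over pairs of libraries. Camera had already set this list against other genes, so the comparison restates that result and is no separate support. Total counts as the scale, the test first chosen, gave -2.11, but they lower all genes and so cannot test a fall. No biological explanation was tested, and fewer divisions, death of dividing cells and a different mix of cells all stay open. The amounts of C. albicans are not given in the sources used here, so form and dose cannot be separated.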

How the results depend on the processing

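The scale by total counts was chosen after seeing the data; the other alternatives were planned. The 9 counts of genes stayed within 1.5 times their value with DESeq2, RLE or total-count scaling, no or a stricter filter, the replicate block, a fit of only the groups compared and each library left out. Asking for a log2 fold change of at least 1 as well, which by construction calls fewer genes, gave 1934 (yeast), 4531 (hyphae), 204 (6 µm), 1080 (25 µm), 2878 (hyphae against yeast), 743 (25 against 6 µm beads), 2389 (the difference of size contrasts), 373 (the same direction in both size contrasts), 110 (all 4 stimuli). Leaving out each library gave 7845 to 7938 (yeast), 10259 to 10432 (hyphae), 3535 to 3783 (6 µm), 6075 to 6244 (25 µm), 9185 to 9336 (hyphae against yeast), 4790 to 5093 (25 against 6 µm beads), 7695 to 7876 (the difference of size contrasts), 2870 to 3183 (the same direction in both size contrasts), 2150 to 2455 (all 4 stimuli), and an r across genes of 0.334 to 0.344. That r was 0.2999 without a filter and 0.471 with a stricter one. With the block it was 0.339, and edgeR fold changes without the block give 0.339, so the step from 0.350 comes from the kind of fold change. With total counts Clec7a in hyphae against yeast turned to -0.20 and Mmp8 in the difference of size contrasts to -0.16; neither had been called with TMM, and the shift of all genes is of that size. Of 112 list calls, 27 were lost with an estimated correlation, 8 with total counts, 1 with the block, 0 with RLE and 4 in at least 1 fit without a library. With camera, lists that had not passed did so in 4 cases: C-type lectin receptors in hyphae against yeast with total counts (adjusted p = 0.0480), neutrophil markers with hyphae without hyphae library 1, 2 or 3 (0.0391, 0.0460 and 0.0477), and with 6 µm beads dendritic cell maturation without unstimulated library 1 or 6 µm library 1 (0.0156 and 0.0193) and neutrophil markers without 6 µm library 3 (0.0497). Of 310 named gene calls, 11 were lost in at least 1 fit without a library. fry, which compares no list with other genes, also passed many lists that camera did not and gave the other direction for C-type lectin receptors in hyphae against unstimulated (adjusted p = 0.00261), alternative activation in hyphae against yeast (1.19e-05) and 25 against 6 µm (2.89e-04), and Th2 and Th9 ligands in the difference of size contrasts (9.20e-04); the cause was not tested. Depth limits Il10 and Il23a in the bead groups, where counts are at or near the floor.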

Other observations

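Some tests in this part were chosen only after the result was seen. They are the correlation used for a stronger stimulus, the setting of interferon-stimulated genes against all genes, and the scaling test of ribosomal protein genes. Total counts as a scale were chosen only after the TMM factors were seen. Beads of both sizes shared 3145 genes that changed against unstimulated cells, 2797 in the same direction and 348 in opposite directions. Independent lists of these lengths would give 1052 and 1046, and 20 simulations of unchanged groups gave 0 at most, as hardly any gene passes without an effect. Both comparisons use the same 3 unstimulated libraries, which favours a shared direction by an amount not measured here. Il1b was one of the genes with opposite directions, at -0.29 ± 0.07 log2 units with 6 µm and 4.16 ± 0.05 with 25 µm beads, and so was Tnf, at -0.27 ± 0.06 and 1.34 ± 0.05. Of these genes 199 were lower with 6 µm and higher with 25 µm beads, and 149 the reverse.

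The comparisons of 3 with 3 libraries allow 10 splits, too few for a share under 0.05. In each, 1 of 10 splits, the real one, gave as many genes: 8294 (yeast), 10544 (hyphae), 4108 (6 µm beads), 6671 (25 µm beads) against unstimulated cells, 9541 for hyphae against yeast and 5515 for 25 against 6 µm beads. With edgeR the highest of the other splits gave 0 in each. These splits mix the real groups, which turns a group difference into spread within groups. A 0 was therefore likely in advance and adds nothing on chance.

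Interferon-stimulated genes were higher with 25 µm than with 6 µm beads. Scaling would move all genes alike, and the median of all tested genes was -0.03 with TMM, against 1.98 for the interferon-stimulated genes. This argues against scaling as the whole cause. Camera had already set the list against other genes, so the comparison restates that result and is no separate support. With total counts, the test first chosen, the median of the interferon-stimulated genes was 1.92 (1.67 to 2.13 over pairs of libraries). That scale shifts all genes of this contrast by only -0.06, so it could not have removed the rise. A stronger stimulus, rather than a larger particle, stays open. The 25 against 6 µm profile correlated at r = 0.548 across genes, which are not independent, with that of yeast against unstimulated cells, with which it shares no library, and a size response that resembles other stimuli may give this too. Bead numbers and coated surface are not given in the sources used here, so size and dose cannot be separated.

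Most ribosomal protein genes were lower with each stimulus than in unstimulated cells, most of all with hyphae, and with total counts as well as with TMM. Genes of like exonic length and level did not fall alike: 10000 random lists matched in both had medians around 0.0784. Their 1st percentile was -0.23, and the ribosomal protein genes lay at -1.03. Exonic length is the union of all annotated exons, with a median of 1770 bases for these genes and 1880.5 for the matched genes. It is not the length of the transcripts present, so loss of short transcripts stays open. Scaling as the whole cause is argued against, since it would move all genes alike. The median of the ribosomal protein genes less that of the other tested genes was -1.02 (-1.07 to -0.92 over pairs of libraries). Both medians were known when this test was chosen, so it restates the fall and is no separate support. Reads shared with the many pseudogenes of these genes were not tested. No biological explanation was tested, and a change in the mix of cells stays open.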
